A study of Drosophila melanogaster with 3 samples.

How the data were processed

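Chromatin immunoprecipitation with sequencing was carried out on whole embryos of Drosophila melanogaster, mixed in sex and 0 to 24 h old, from a transgenic line that carries Nf-YB with green fluorescent protein at its C-terminal end. Nf-YB is the B subunit of NF-Y, a trimeric transcription factor known to recognise the CCAAT box. Per the labels, an antibody against the fluorescent tag was used, chromatin was sheared by sonication and fragments ran from 200 to 800 bp. The labels number 3 biological replicates, each with 1 technical replicate, and these form 1 group. No other condition was analysed here, so every comparison is between replicates, between peaks and control positions in the genome, or between lists of genes.

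Per the file headers and readme texts of the samples, the authors called peaks on each replicate's alignment against 1 control alignment, called a pooled list on the alignments of all 3 replicates against the control, and derived an optimal list of reproducible peaks from the replicate lists and the pooled list by the irreproducible discovery rate. The assembly is dm6 per the labels. The aligner, the peak caller, their versions and the threshold of the irreproducible discovery rate are not given in the sources used here. The control alignment was not used here. Each deposited list gives an interval, a signal value, a −log10 q-value and a summit per peak. The signal value is the authors' own score for a peak, its relation to depth is not given, and it served only to rank peaks within a list. The deposited −log10 q-value served only as an alternative ranking. A p-value per peak is not given in the deposited lists. Each replicate list and the pooled list holds 30000 peaks, so list length carries no information on the libraries. The read depth of each replicate is unknown from these files, and no interval that needs read depth was computed. All 6221 peaks of the optimal list are the 6221 pooled peaks with the highest signal. Of these, 163 share their interval with an earlier peak of the list and differ in the summit; each summit was counted. Summits outside their own interval made up at most 0.01% of any list and were kept.

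The sequence used was the RefSeq copy of the assembly, and genes came from Ensembl release 115. Arm lengths contain every peak, and 30540 of 30593 annotated start codons (99.8%) read ATG at their annotated position. Genes on the 6 arms 2L, 2R, 3L, 3R, 4 and X were used, 18164 in all and 13945 of them protein-coding, and annotated transposable elements were left out. Positions are given in dm6 and counted from 1.

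To compare replicates at equal length, the 6221 peaks with the highest signal of each replicate were taken. Peaks were called shared when their summits lay within 100 bp, and 100 random placements on the same arm gave the chance level. A summit within 500 bp of an annotated transcription start site (TSS) was counted as a promoter peak, and 1000 random placements of the summits on the same arm outside assembly gaps gave the expected share with a two-sided permutation p. The smallest p these placements can give is 0.000999. Other summits were placed in 5' UTR, coding exon, 3' UTR, other exon, intron or intergenic sequence, in that order. Motifs on either strand were searched within 50 bp of the summit and in windows of the same size centred 500 bp to both sides, and a two-sided exact McNemar test compared the summit window with 1 side window picked at random. Benjamini-Hochberg adjustment covered the 15 motifs. The relation of CCAAT to signal was tested by a two-sided permutation test with 100000 permutations, whose smallest p is 1e-05. Gene lists, 28 in number, were tested by a two-sided Fisher's exact test of genes with a promoter peak against all other protein-coding genes (for tRNA genes, against all other genes), with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Where genes were stratified by their number of TSSs or by promoter GC, the Cochran-Mantel-Haenszel chi-square test was used, which is an approximation. Genes with 3 or more TSSs formed a single stratum. Of 405 gene symbols written in the lists, 3 matched no single gene and were left out. Intervals on shares are exact Clopper-Pearson intervals at 95% and cover counting of peaks or genes only. Peaks and genes are not replicates, so these p-values describe the lists of this experiment, and replicate spread is given as mean ± SD over the 3 replicates.

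The groups, lists, motifs, tests and most alternatives were fixed before the data were examined, and the alternatives added later are named as such in the closing part. Named peaks follow a rule fixed at the same time. It takes the 20 optimal peaks with the highest signal that lie within 100 bp of a summit in the top 6221 of all 3 replicates, each named by the gene with the nearest TSS (a protein-coding gene first within 500 bp). It takes the 4 bound genes with the highest signal from each list past the threshold and 2 from each other list. It also takes Nf-YA, Nf-YB, Nf-YC, bsk, sens, sev and p53, bound or not. An item that this rule takes is not reported here. Alternatives covered the summit distance, the number of peaks, the ranking, the promoter window, the motif window and its control, the peak list, the number of TSSs per gene, neighbouring genes and leaving out each replicate. For the last, the peaks shared by the top 6221 of the remaining replicates replaced the optimal list. These lists held 3883, 4005 and 4397 peaks without replicates 1, 2 and 3.

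The statistics were tested on simulated data. With 60.0% of 6221 summits planted as shared between lists, 60.3% were recovered. CCAAT written at random genomic summits to a share of 27.9% was recovered at 27.9%, and random summits without it gave an exact McNemar p = 0.855. Randomly bound genes gave calls by Fisher's exact test, adjusted over the lists, in 0.185% of list tests over 13945 genes. With binding that rose with the number of TSSs and no list effect, the stratified chi-square test called the segmentation list in 4% of draws over 13945 genes at an unadjusted threshold of 0.05. By Fisher's exact test, lists of 20 or more genes in which a member not already bound had an even chance of being made bound were called in 92.0% of draws. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.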

Results

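Binding of GFP-tagged Nf-YB was profiled in whole embryos of 0 to 24 h in 3 biological replicates of 1 group. The authors' optimal list held 6221 peaks, with a median width of 444 bp. Exactly this width was given for 53.3% of them and for 89.8% of the pooled list, so the median says little on how peak widths vary. Depth is unknown, since the lists carry no read counts. Signal values are the authors' and are given relative to the median signal of the optimal list or as ranks.

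Genes of transcription factors, of Polycomb group proteins and of a chaperone were among those at the 20 strongest peaks. The peak with the highest signal, 158 times the list median, lay 300 bp upstream of a TSS of opa (FBgn0003002), a pair-rule zinc finger gene, at 3R from 4851798 to 4853129 in intergenic sequence, and it ranked 1 in each replicate. The peak ranked 2, at 4 from 989038 to 990166, lay 174 bp upstream of toy (FBgn0019650), a Pax6 gene of eye development, and the other Pax6 gene, ey (FBgn0005558), held the peak ranked 10, 127 bp upstream of a TSS and within an intron of the gene. Both Polycomb group genes of a neighbouring pair were in this set, with Psc (FBgn0005624) at rank 3 (2R from 12979483 to 12981745, summit in the 5' UTR) and Su(z)2 (FBgn0265623) at rank 8 (2R from 12995866 to 12997667, intergenic). The homeobox genes lbe, scro, mirr, caup, inv, C15 and ap, the forkhead gene fkh and the tracheal gene trh held the ranks 7, 9, 11, 12, 13, 16, 20, 17 and 14. Calr (FBgn0005585), which encodes the calcium-binding chaperone calreticulin, was the gene at rank 6, with the summit 82 bp upstream of a TSS at 3R from 9629988 to 9631775.

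The summits at mirr and trh lay 629 and 808 bp upstream of a TSS, and those of the peaks ranked 4, 5, 15, 18 and 19 lay farther away. The nearest TSSs of these 5 were those of E5 at 2387 bp, CG13321 at 2484 bp, CG13323 at 4994 bp, the opsin gene Rh5 at 1899 bp and lncRNA:CR44678 at 3006 bp, and all were intergenic. Of the 20 peaks, 13 had the summit within 500 bp of a TSS, 12 carried CCAAT within 50 bp of the summit and 14 carried GAGAG. Their signals ran from 81.0 to 158 times the list median, and none ranked below 40 in any replicate.

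The replicates shared most of their strongest peaks. Replicates 1 and 2 shared 70.7% of their 6221 highest peaks, replicates 1 and 3 shared 64.4%, and replicates 2 and 3 shared 62.4%, a mean of 65.8% ± 4.32 (SD over 3 pairs). Random placement gave 0.922% to 0.936%. Among the 100 highest peaks, which include those at opa, toy and Psc, the mean share was 91.3% ± 4.93. Across peaks of the optimal list, which are not independent replicates, Spearman's rho of the replicates' signals was 0.844 for replicates 1 and 2, 0.642 for replicates 1 and 3 and 0.649 for replicates 2 and 3. Replicate 3 thus stood apart from the other 2 in both measures. Mean GC content at the summits of the 6221 highest peaks was 41.0%, 41.7% and 37.3% in replicates 1, 2 and 3.

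**Figure D1:**
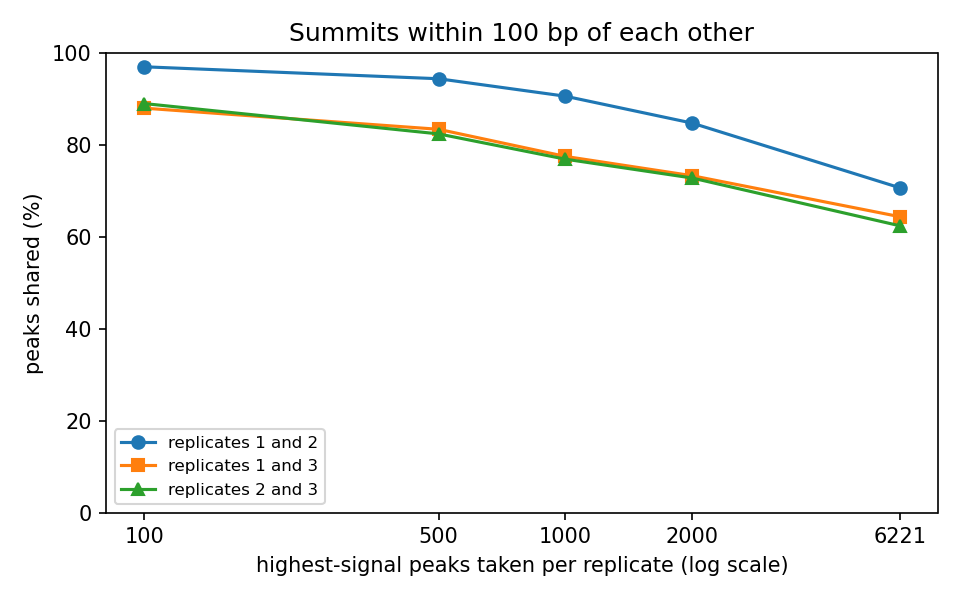
Share of peaks (%, y axis) with summits within 100 bp of each other for each pair of replicates, against the number of highest-signal peaks taken per replicate (x axis, log scale). Replicates 1 and 2 shared 97.0% of their 100 highest peaks and 70.7% of their 6221 highest, and both pairs with replicate 3 lay lower at each number.

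Of the optimal peaks, 3394 (54.6%, interval 53.3 to 55.8) were found among the 6221 highest peaks of all 3 replicates, 1744 in 2 replicates, 1009 in 1 and 74 in none. Per replicate the share found was 78.7% ± 2.52 (SD, n = 3). Of the 622 optimal peaks with the highest signal, 615 were found in all 3. The share in all 3 replicates was 31.4% when 0.5 times as many peaks were taken per replicate. All 6221 optimal peaks stayed in that count, so the shorter replicate lists cap the share and its fall does not measure agreement. The mean share between pairs of replicates at that length was 73.1%.

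Promoters held 2802 of the 6221 optimal peaks, or 45.0% (interval 43.8 to 46.3), against 13.6% ± 0.426 (SD over placements) for random positions on the same arms, 3.32 times as many (two-sided permutation p = 0.000999, the smallest these placements can give). The 3 replicates gave 45.2% ± 1.57 (SD, n = 3). Promoter summits lay mostly in front of the TSS, with 2154 of 2802 (76.9%) upstream, 1453 (51.9%) within 200 bp upstream, and a median position of -104 bp. Introns held 32.8% of peaks against 39.5% of random positions, and intergenic sequence 19.1% against 27.1%. Promoters were assigned first, so the larger promoter share leaves less for the other classes. These 2 lower shares thus do not by themselves show that peaks avoid introns or intergenic sequence. Coding exons held 35 peaks, or 0.563% (interval 0.392 to 0.782), against 13.8% of random positions, and 3' UTRs held 0.707% against 4.45%. Across replicates the coding exon share was 0.675% ± 0.255 and the intron share 32.3% ± 0.890 (SD, n = 3).

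Peak density on the major arms was 48.6 peaks per megabase on 2L, 45.2 on 2R, 45.3 on 3L, 47.7 on 3R and 46.1 on X. Density on X was 0.987 times that of the 4 major autosomal arms, and 0.975 ± 0.0220 in the replicates (SD, n = 3). Chromosome 4, which carries toy and ey, held 57 peaks or 42.8 per megabase. Its replicate mean was 46.6 ± 14.5 per megabase (SD, n = 3), from 70, 76 and 40 peaks in replicates 1, 2 and 3.

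The CCAAT box, the sequence NF-Y is known to recognise, was more frequent at summits than beside them. It lay within 50 bp of the summit in 1679 of 6221 optimal peaks, 27.0% (interval 25.9 to 28.1), against 18.5% of the side windows (two-sided exact McNemar p = 1.61e-27). The share depends on the window, with 15.5% against 9.63% within 25 bp. Replicates gave 26.7% ± 0.587 at summits and 18.4% ± 0.219 beside them (SD, n = 3). The longer form RRCCAATSR was found at 5.80% of summits and 0.852% of side windows, a ratio of 6.81 (adjusted p = 9.16e-56, exact McNemar). CACAT, a permutation of the CCAAT letters, was found at 20.4% and 21.5% (adjusted exact p = 0.349), although against shuffled summit windows that keep dinucleotide counts CACAT was also more frequent (log2 ratio 0.12, adjusted exact p = 0.0324), as CCAAT was (27.0% against 19.0%, exact p = 2.09e-28). At promoter peaks the CCAAT share was 24.2%, against 18.7% at promoters without an optimal peak in windows at matching distances to the TSS (two-sided Fisher's exact p = 6.12e-07). Peaks away from promoters carried CCAAT more often, at 29.3% (Fisher's exact p = 5.69e-06 against promoter peaks).

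Other elements also marked the summits. The GAGA element GAGAG, bound by the GAGA factor, was found at 18.0% of summits and 13.3% of side windows (adjusted exact McNemar p = 2.35e-09), the DNA replication-related element at 1.22% and 0.281% (adjusted p = 6.45e-08), and core promoter Motif 1 at 0.675% and 0.0723% (adjusted p = 7.37e-08). The BEAF core was found at 14.0% and 11.6% (adjusted exact p = 7.43e-06) and the TATA box at 3.81% and 2.47% (adjusted p = 3.96e-06). The BEAF core CGATA is part of the DNA replication-related element TATCGATA, so each site of that element counts for both. Against the shuffled windows the TATA box did not pass (adjusted exact p = 1.00), and among the 3110 peaks with the highest signal the BEAF core did not (adjusted p = 0.122). The Zelda site, CACGTG, the E2F site, the CRE, the initiator, Ohler Motif 6 and the GC box did not pass the threshold, with adjusted exact p from 0.0776 for Motif 6 to 0.933 for the initiator. Motif 6 was more frequent in a window of 100 bp (adjusted exact p = 0.000417), against controls 1000 bp away (0.0320) and against shuffled windows (0.0149). The GC box was less frequent against controls 1000 bp away (adjusted exact p = 0.0121), and against shuffled windows CACGTG was less frequent (0.0149) and the E2F site more frequent (0.0150). The initiator was more frequent at promoter peaks alone, a choice made after seeing the data (adjusted exact p = 0.0408).

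CCAAT was most frequent at the strongest peaks. Its share was 38.5% (interval 35.8 to 41.2) in the fifth of the list with the highest signal, 26.3%, 25.9% and 22.7% in the next 3 parts and 21.6% (19.4 to 24.0) in the fifth with the lowest, while side windows stayed between 17.6% and 19.5%. Across peaks, rho of signal with CCAAT presence was 0.128 (two-sided permutation p = 1e-05, the smallest these permutations can give), and 0.119 ± 0.00678 in the replicates (SD, n = 3). Without the tenth of the list with the highest signal, an alternative chosen after seeing the data, rho was 0.0579 (permutation p = 3e-05). The strongest peaks at opa, ey, lbe, caup, inv, fkh and Calr carried CCAAT at the summit, and those at toy, Psc, Su(z)2, scro, mirr, trh, C15 and ap did not.

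**Figure D2:**
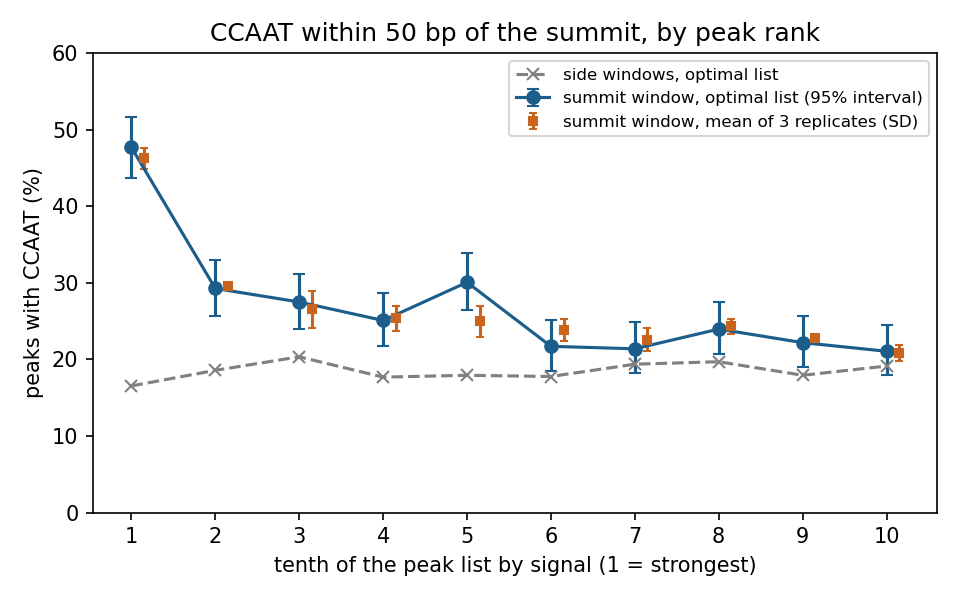
Share of peaks with CCAAT within 50 bp of the summit (%, y axis) in 10 parts of equal size of the list by signal (x axis, 1 is the strongest), for the optimal list with 95% Clopper-Pearson intervals, for the 3 replicates as mean and SD, and for side windows of the optimal list. The part with the highest signal reached 47.7%, against 16.5% in its side windows.

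Which groups of genes carried a peak at their promoters was asked with lists fixed in advance. Of 13945 protein-coding genes, 3017 (21.6%) were bound, and the replicates gave 2917 ± 253 (SD, n = 3). Of 28 lists, 7 were bound more often than other genes and 5 less often.

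Segmentation genes, which divide the embryo into segments, were bound in 24 of 26 cases (92.3%, adjusted p = 1.97e-13, Fisher's exact test), and 24.0 ± 1.00 were bound in the replicates. Beside opa, the strongest were slp2 at rank 44, 144 bp upstream, odd at rank 54, 74 bp upstream, and eve at rank 65, 85 bp upstream. Hox genes, which set segment identity, were bound in 7 of 8 cases (87.5%, adjusted Fisher's exact p = 0.000501) and in 7 in each replicate. Among them lab, Dfd, Scr and pb had ranks 177, 178, 192 and 290 on 3R, and the peak at lab (3R from 6678319 to 6679031, intergenic) lay 82 bp upstream with a signal 21.2 times the list median. Of 27 Hox and segmentation promoter peaks among the 622 with the highest signal, 5 carried CCAAT at the summit. No summit of replicate 1 lay within 100 bp of the one at pb. Dorsoventral and mesoderm genes were bound in 16 of 23 cases (69.6%, adjusted exact p = 6.3e-06), with Doc3 at rank 24, tin at 40, pnr at 45 and Doc1 at 66. Neural genes were bound in 11 of 23 cases (47.8%, adjusted exact p = 0.0148), with SoxN at rank 21, D at 35, repo, a glial gene, at 89 and gcm at 97. The neural list did not pass when genes were stratified by their number of TSSs (adjusted p = 0.127, Cochran-Mantel-Haenszel chi-square test) or with a promoter window of 250 bp (adjusted p = 0.0975, Fisher's exact test).

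Ribosomal protein genes were bound at lower ranks. Of the 93 cytosolic ribosomal protein genes 72 were bound (77.4%, adjusted p = 5.15e-29, Fisher's exact test), and 69.7 ± 2.52 in the replicates (SD, n = 3). Among the strongest were RpL7 at rank 972, RpS27 at 1020 and RpL14 at 1023, with summits 46, 11 and 4 bp from a TSS. CCAAT was found at 18 of the 77 summits at these genes. Genes of folding and stress in the endoplasmic reticulum were bound in 17 of 27 cases (63.0%, adjusted exact p = 1.97e-05), with Calr at rank 6, Xbp1 at 491, Hrd3 at 692 and Hsc70-3 at 1805. Among the 3110 peaks with the highest signal 7 of 27 were bound and the test did not pass (adjusted exact p = 0.0819). Insulator and GAGA factor genes were bound in 8 of 16 cases (adjusted exact p = 0.0314), with Chro at rank 96, Cp190 at 686, M1BP at 939 and Dref at 1601. This list did not pass when stratified by the number of TSSs (adjusted p = 0.0932, chi-square), with a window of 1000 bp (adjusted p = 0.0728, exact) or without genes that lie near another gene's TSS (1 of 5 bound, adjusted p = 0.653, exact).

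Receptor, cytochrome P450, tRNA, cuticle and testis genes were bound less often than other genes. Of 176 odorant and gustatory receptor genes, 1 was bound (adjusted p = 1.87e-16, Fisher's exact test), Gr63a at rank 6162. Of 81 cytochrome P450 genes 4 were bound (adjusted exact p = 0.000238), namely Cyp12a5, Cyp6u1, Cyp317a1 and Cyp6v1 at ranks 893, 1303, 4939 and 5807. Of 295 tRNA genes 17 were bound against 18.8% of all other genes (adjusted exact p = 1.32e-09), led by tRNA:Tyr-GTA-1-8 at rank 689, tRNA:Phe-GAA-1-2 at 1719, tRNA:Gln-TTG-2-1 at 2181 and tRNA:Val-CAC-2-5 at 3041. tRNA genes are multi-copy, so their peaks are uncertain, and 44, 17 and 15 were bound in replicates 1, 2 and 3. None of 20 cuticle protein genes (adjusted exact p = 0.0314) and none of 19 testis genes (adjusted p = 0.0489) was bound, in the optimal list or in any replicate. Neither call held among the 3110 peaks with the highest signal (adjusted exact p = 0.26 for both), among peaks shared by all 3 replicates (0.322 for both), with a window of 250 bp (0.0780 for both), without genes near another gene's TSS (0.127 and 0.237) or without any 1 replicate (0.141 to 0.216). Stratified by the number of TSSs the chi-square test gave adjusted p = 0.127 and 0.126, and with neighbouring genes counted once the testis call was lost (adjusted exact p = 0.0596). None of these genes was bound in any of these settings. The calls were thus lost through the other genes, the number of members, or the test and its adjustment.

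The other 16 lists did not pass. General transcription genes were bound in 12 of 31 cases (adjusted exact p = 0.0604), with Taf5 and Taf2 the strongest, mitochondrial ribosomal protein genes in 24 of 73 (adjusted p = 0.0622), with mRpL30 and mRpS10, and Polycomb and Trithorax genes in 10 of 26 (adjusted p = 0.0873), with Psc and Su(z)2. When stratified by the number of TSSs, general transcription (adjusted p = 0.0210, chi-square) and mitochondrial ribosomal proteins (0.00393) passed. With neighbouring genes counted once both passed (adjusted exact p = 0.0241 and 0.00346), as did Polycomb and Trithorax (0.00491). Polycomb and Trithorax also passed with a window of 1000 bp (adjusted exact p = 0.0170) and without replicate 2 (0.00909), general transcription with a window of 250 bp (0.0444), and mitochondrial ribosomal proteins with optimal peaks found in at least 1 replicate (0.0460), a choice made after seeing the data. Ovary genes of chorion and yolk were bound in 0 of 17 cases (adjusted exact p = 0.0622, and 0.0250 with a window of 1000 bp) and opsin and adult phototransduction genes in 0 of 15. Heat shock and cytosolic chaperone genes were bound in 11 of 32 cases, with Hsp27 and Hsp83, muscle structure genes in 6 of 16, with sls and Msp300, and immune genes in 2 of 20, PGRP-LE and Rel. Mitotic cell cycle genes were bound in 9 of 33 cases, with CycE and Cdk1, DNA replication genes in 8 of 37, with RnrS and Cdc7, and proteasome genes in 9 of 32, with Rpn3 and Rpn13. Oxidative phosphorylation genes were bound in 17 of 87 cases, with ND-ASHI and ND-MWFE, mediator genes in 6 of 25, with MED30 and MED27, and replication-independent histone genes in 1 of 6, His2Av.

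**Figure D3:**
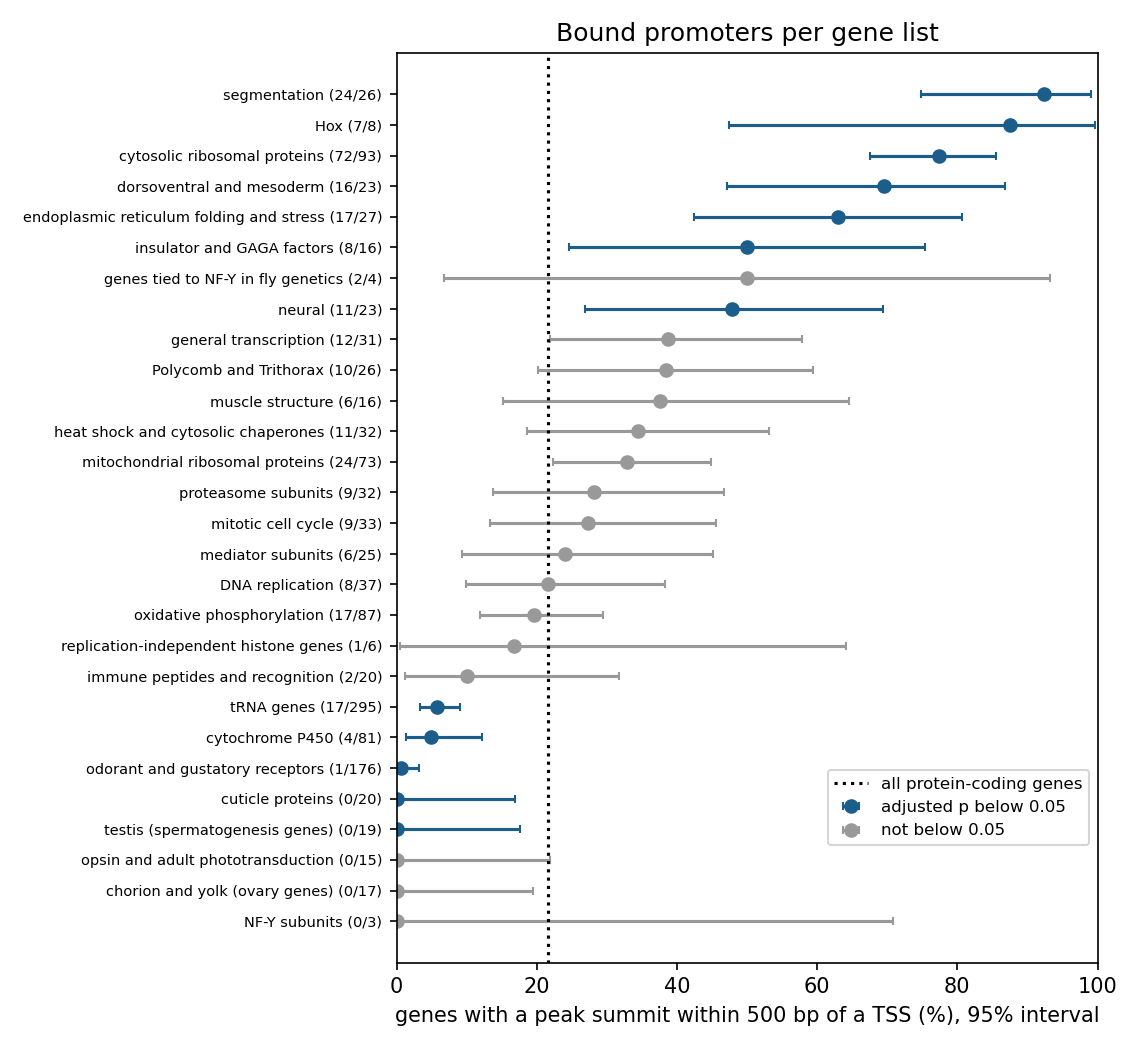
Share of genes with a peak summit within 500 bp of a TSS (%, x axis) for each of 28 gene lists (y axis, bound and total genes in parentheses), with 95% Clopper-Pearson intervals. The dotted line marks 21.6% for all protein-coding genes, and blue points, among them segmentation at 92.3% and cytosolic ribosomal proteins at 77.4%, passed the adjusted threshold. tRNA genes were tested against all other genes, not against the dotted line.

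The genes of the NF-Y trimer itself carried no optimal peak at their promoters (0 of 3). At Nf-YA, on 3L from 9440056 to 9442267, the pooled list had 2 promoter peaks below the optimal list, the stronger at rank 11196 of 30000, and all 3 replicates had at least 1. Nf-YB, on 2L from 19736044 to 19737088, had none in any list. Nf-YC, on X from 6818178 to 6820919, had 1 in replicate 2 only, at rank 13096. Of 4 genes tied to NF-Y in fly genetics, 2 were bound (adjusted exact p = 0.289). At sens, which encodes a zinc finger factor of sensory organs, the summit lay 138 bp upstream of a TSS in intergenic sequence at rank 473 (3L from 13400961 to 13401523), and at p53 it lay 55 bp upstream at rank 3097 (3R from 23054087 to 23054199). Both summits of the optimal list carried CCAAT, while the replicates' own summits carried it in replicates 1 and 2 and not in 3 at sens, and in replicate 3 and not in 1 or 2 at p53. The kinase gene bsk and the receptor kinase gene sev had no promoter peak in any list.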

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

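Pooled peaks outside the optimal list, which the report used only to look up single genes, also carried the motif. At the summits of the 23779 pooled peaks below the optimal list CCAAT was found in 21.0% (interval 20.5 to 21.5) against 18.5% of side windows (exact McNemar p = 2.64e-10), and RRCCAATSR in 1.90% (1.73 to 2.08) against 0.919% (p = 9.38e-21). Both were singled out because they exceed the level beside the summits in peaks whose motifs the report did not give as a set. Groups of 3 samples were not tested for outlying samples, and with 1 group no difference between groups exists to test.

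The stratification by the number of TSSs was fixed in advance, as an alternative test, and the other tests of explanations below were chosen after the patterns had been seen. What each would show was written before its own result for the tests of GC content and of whole intervals, and after it for both comparisons of CCAAT shares and the stratification by the number of TSSs. GC strata moved lists little, with a shift in the log2 odds ratio of 0.1 or more for 3 of 14 other lists with at least 5 bound genes, and 16.2% to 24.6% of genes were bound per stratum. These values and the shares that GC alone would give were chosen after all other results had been seen. The design has 1 group, so no explanation by a difference between conditions was tested, and the CCAAT tests concern only the motif at or near these peaks.

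Replicate 3 stood apart from replicates 1 and 2. Among the 1000 highest peaks of each, 195 peaks of replicate 3 were absent from both others and 166 were shared by replicates 1 and 2 and absent from replicate 3. Mean GC at the summits was 30.4% in the first set and 49.0% in the second, a difference of -18.2 percentage points within promoter class (bootstrap interval -20.5 to -16.0), and the 1000 highest peaks had a mean GC of 47.9%, 48.0% and 44.0% in replicates 1, 2 and 3. The first set needed 1 replicate and the second needed 2, so peaks of a single replicate were also set against reproduced peaks. Peaks high in replicate 1 alone or in replicate 2 alone were not examined. The means over the 1000 highest peaks do not rest on these sets. A GC-dependent step in making or sequencing the library of replicate 3 may account for part of its distance, although peaks that differ in kind could differ in GC too. Promoters made up 62.1% of the first set and 32.5% of the second. The difference was taken within promoter class, so these unequal shares do not produce it. Which library departs from the true profile is left open.

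Peaks at Hox and segmentation promoters were mostly strong, with 7 of 9 and 20 of 28 in the tenth of the list with the highest signal. Of 27 such peaks among the 622 with the highest signal, 5 carried CCAAT (18.5%, interval 6.30 to 38.1). Of the other 595, 49.1% did (Fisher's exact p = 0.00247). A CCAAT box at the summit thus marked the 27 less often than these 595. The 595 include peaks away from promoters, so promoter class is mixed into this contrast. In the optimal list CCAAT was found at 29.3% of peaks away from promoters and 24.2% of promoter peaks. The 27 were not compared with strong promoter peaks of other genes alone. From promoter GC alone 20.7% of the Hox and segmentation genes would be bound, against 91.2% observed (interval 76.3 to 98.1). The log2 odds ratio was 5.15 with 5 GC strata and 5.04 without, which argues against promoter GC as the whole cause. Whether a CCAAT box elsewhere in these wide peaks was missed stays open: CCAAT was 0.989 times as dense inside the intervals as beside them (interval 0.676 to 1.43), a range that includes the 1.31 of other strong peaks. Enrichment at accessible promoters regardless of the tagged protein was not tested, since no library without the tag was used here.

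Cytosolic ribosomal protein promoters were bound as a group. Their log2 odds ratio was 3.48 when stratified by the number of TSSs, against 3.64 without strata. This argues against that number, as far as these strata resolve it, as the whole cause. Promoter GC, on average 41.8% at these genes and 42.7% at others, would alone give 20.6% bound, against 77.4% observed (interval 67.6 to 85.4), and the log2 odds ratio was 3.69 with GC strata. CCAAT was found at 23.4% of their 77 summits (interval 14.5 to 34.4), against 13.6% beside them (exact McNemar p = 0.210) and 21.8% of other promoter peaks in the same range of ranks. With 77 peaks, whether CCAAT is more frequent at these summits than beside them stays open. Enrichment at these promoters regardless of the tagged protein was not tested either, since no library without the tag was used here.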

How the results depend on the processing

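The alternatives of rank agreement, genomic class and chromosome arms, the lists from optimal peaks found in at least 1 replicate, motifs in promoter peaks only and CCAAT against rank without the strongest peaks were chosen after seeing the data. No paired analysis was possible because the samples form 1 group. Taking the 6221 highest pooled peaks changed nothing, since these are the optimal list. The promoter share, the CCAAT share and its relation to rank kept direction and threshold under every alternative run, with promoter shares from 35.2% at 250 bp to 55.1% at 1000 bp and CCAAT shares from 15.5% at 25 bp to 41.5% at 100 bp. The number of lists past the threshold ran from 9 to 14 and of motifs more frequent at summits from 6 to 9. Read depth is unknown, so what it limits cannot be stated.

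The mean share of peaks shared by 2 replicates was 54.2% within 50 bp, 73.7% within 250 bp, 74.9% for overlap by 1 bp, 73.1% with 0.5 times and 58.5% with 2 times as many peaks, and 62.4% to 70.7% without 1 replicate. Optimal peaks found in every replicate came to 42.9%, 62.4%, 63.1%, 31.4% and 79.0% under the same settings, and to 61.0% to 67.1% without 1 replicate, where fewer lists are required. Mean rho of signals ran from 0.642 to 0.844 without 1 replicate. Introns held 30.3% of the 3110 strongest peaks, 31.4% of peaks shared by all replicates and 31.0% to 32.8% without 1 replicate. Density on X over the major autosomal arms was 1.02 for peaks shared by all replicates and 0.986 to 1.03 without 1 replicate. Looser overlap and other list lengths by construction move shared counts, and otherwise the cause was not tested.

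Signs turned only for motifs and lists that did not pass the threshold, here as log2 ratios and log2 odds ratios. Apart from the constant added to each count, named below, the cause was not tested. Within 100 bp the Zelda site gave 0.0868, the CRE 0.36 and the initiator -0.00197. Controls 1000 bp away gave -0.0178 for the E2F site. Shuffled windows gave 0.12 for CACAT, which then passed, 0.20 for the Zelda site, 0.20 for the CRE and 0.25 for the GC box. Among the 3110 strongest peaks the Zelda site gave 0.25, the CRE 0.48, the initiator -0.0462 and the GC box 0.21, and at promoter peaks the E2F site gave -0.0408 and the CRE 0.30.

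Among lists, a window of 250 bp gave 0.35 for replication-independent histones and -0.31 for muscle structure, and 1000 bp gave -0.20 for DNA replication. Leaving out genes near another TSS gave -0.27 for mitotic cell cycle and -1.37 for mediator. Counting neighbours once gave 0.18 for histones and 0.14 for oxidative phosphorylation, and optimal peaks found in at least 1 replicate gave 0.00470 for histones. The 3110 strongest peaks gave 0.14 for NF-Y subunits, -0.71 for mitotic cell cycle, 0.0575 for immune genes and -0.67 for proteasome. Peaks shared by all replicates gave 0.0560 for NF-Y subunits, -1.58 for mitotic cell cycle, -0.0329 for DNA replication, -0.16 for general transcription and -1.53 for proteasome. In both settings 0 of 3 NF-Y subunits were bound, as in the main run, so their positive values come only from a constant added to each count. For histones 1 of 6 was bound in the main run and for the values of 0.35, 0.18 and 0.00470. The same constant lifts all of these values. DNA replication genes were bound in 21.622% of cases in the main run, against 21.635% of other genes. Their positive main value therefore comes only from this constant. Leaving out 1 replicate at a time gave -1.07 to -0.23 for mitotic cell cycle, -0.31 to 0.21 for DNA replication and -1.02 to 0.16 for proteasome. The range was -1.11 to 0.61 for histones, -0.18 to 0.59 for heat shock and -0.0943 to 0.59 for mediator. The sign turned without any of the 3 replicates for mitotic cell cycle, without replicate 1 or 3 for DNA replication and proteasome, without replicate 2 for histones and heat shock and without replicate 3 for mediator. The lists of shared peaks used here were shorter than the optimal list. A turn thus cannot be told apart from an effect of list length.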

Other observations

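The tests and values in this part were chosen after the main results had been seen, and for the test of both motifs together the prediction was written before its result was known.

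The GAGA element was frequent at the strongest peaks. In the tenth of the optimal list with the highest signal 39.3% of summits carried GAGAG (interval 35.5 to 43.3) against 12.8% of side windows, and in the next 622 peaks 18.5% against 15.2%. At Hox promoters 7 of 9 summits carried GAGAG and 1 carried CCAAT, with 22.2% of side windows for either motif. At segmentation promoters 17 of 28 carried GAGAG (side windows 7.14%) and 5 carried CCAAT (19.6%). Among strong Hox and segmentation peaks GAGAG was found in 63.0%, against 38.3% of the other 595 of the 622 peaks with the highest signal (Fisher's exact p = 0.0145). The other 595 include peaks away from promoters, so promoter class is mixed into this contrast. Dorsoventral and mesoderm promoters had CCAAT at 9 of 20 summits (side windows 5.00%) and GAGAG at 6 (10%). Cytosolic ribosomal protein promoters had GAGAG at 4 of 77 summits (side windows 10.4%) and CCAAT at 18 (13.6%).

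Whether CCAAT and GAGAG mark different peaks among the 622 with the highest signal was a hypothesis that the test left open. Of 622 peaks, 108 carried both, 189 CCAAT alone, 137 GAGAG alone and 188 neither, an odds ratio of 0.784 (Fisher's exact p = 0.163). Peaks with GAGAG alone lay at promoters in 55.5% of cases (interval 46.7 to 64.0), and peaks with CCAAT alone in 40.7% (33.7 to 48.1).

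The peaks high in replicates 1 and 2 and not in replicate 3 carried GAGAG in 30.1% of cases (interval 23.3 to 37.7), and those high in replicate 3 alone in 9.23% (5.56 to 14.2). CCAAT was found in 36.7% (29.4 to 44.6) and 24.1% (18.3 to 30.7) of the same sets. Mean GC at the summits of these sets was 49.0% and 30.4%, and no side windows or GC-matched sites were searched for them. Base composition therefore cannot be told apart from a difference in bound elements. The first of these sets also needed 2 replicates and the second 1, which is mixed into these contrasts too. Distinct summits near tRNA genes numbered 28, 12 and 12 in the 6221 highest peaks of replicates 1, 2 and 3.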
